A study of Arabidopsis thaliana with 9 samples.

How the data were processed

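RNA-seq libraries of whole Arabidopsis thaliana seedlings were compared in 3 groups of 3: Col-0, bbx2021 and smax1smxl2. Per the labels, seedlings were kept for 4 days at 22 °C under red light after 2 days at 4 °C, and RNA was selected with oligo(dT), primed with random hexamers and sequenced by a BGISEQ-500 protocol. No strand is stated, so counts of genes that overlap another gene are uncertain. As deposited, each file lists per gene an expected count, a fractional count that the authors made with RSEM. The authors' processing notes name HISAT, Bowtie2 2.2.5, RSEM 1.2.12 and the TAIR10 genome, without the role of each aligner. The FPKM values beside them were deposited by the authors from the same software, and their normalisation beyond gene length and depth is not given in the sources used here. Only genes above 0 are listed, and unlisted genes were set to 0. Expected counts were rounded to whole numbers. Library totals lay between 22608018 and 25230110, and 24640 genes were listed in at least 1 library. Gene symbols came from the files (10056 genes) or a reference annotation (53 genes), and list members without either kept the symbol of their list.

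Counts were normalised by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood test after filterByExpr, which left 20763 genes, with all 9 libraries in 1 fit. Genes with a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 3 comparisons were called: each mutant against Col-0 and smax1smxl2 against bbx2021. Log2 fold changes are given with a standard error derived from the F statistic, and levels as CPM, the counts scaled to a common library size with TMM factors, with the SD. With 3 libraries per group the precision of a value is that of the spread between libraries. A group at 0 was set to 3 counts over the group for a lower bound. The replicate numbers did not pair the libraries, since only 2 of 9 libraries resembled most the libraries of the same number in the other groups.

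The comparisons, the test, 19 gene lists and the rule for named genes were chosen before the data were examined. The lists covered karrikin and strigolactone signalling, other BBX genes, light signalling regulators, flavonoid and anthocyanin enzymes and regulators, photosystem, antenna and Rubisco genes, chlorophyll synthesis, auxin, gibberellin, brassinosteroid, ethylene, cell wall loosening, clock, heat and cold, jasmonate and salicylate, and markers of root hairs, roots, stomatal lineage and seed storage. Members listed in no library or with too few counts, such as BBX23, PR1, PR2 and PR5, were not tested. The jasmonate and salicylate list was thereby left with jasmonate genes only. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over 38 tests, then with an estimated correlation, and beside it with fry, which tests whether genes of a list move 1 way on balance. Camera compares a list with the other tested genes, and fry makes no such comparison. Named genes were the 4 mutated genes, up to 4 called members per list with the largest change or the 2 most abundant where none was called, the 6 called genes with the largest change each way per mutant, 3 each way between the mutants, and 5 opposite and 5 same-direction genes called in both. A gene of the ethylene list that this rule takes is not reported here. The last groups needed a symbol, a mean of at least 50 counts in the group where the gene was higher, and libraries that do not overlap.

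Other settings, also fixed at that stage, were DESeq2 1.42.0, its size factors, upper-quartile factors, no filter or a filter of at least 50 counts in 3 libraries, a fit of only the groups compared, the replicate number as a block, limma 3.58.1 (limma-trend) on log2 FPKM with a pseudocount of 1 or 0.1, stricter thresholds, and leaving out each library. TMM factors were not applied to FPKM, so a call or sign that changes with limma on FPKM may reflect the scaling of the libraries. Offsets for gene length, for length and GC content (lowess with a span of 0.3), those without smax1smxl2 replicate 1, and the mitochondrial share as a covariate were added after the data were seen. The mitochondrial share was 0.0148% to 0.0162% in Col-0, 0.0189% to 0.0373% in bbx2021 and 0.0205% to 0.0452% in smax1smxl2. The covariate can therefore take up part of the genotype difference itself. Gene results were recomputed for the mutated genes, for named genes in comparisons where they were called, and for members named from lists without a call. That restriction was made after first results were seen. Expected overlaps were computed for independent lists and from 10 simulations of unchanged groups that share the Col-0 libraries. The fit was tested on simulated data of 20656 genes, where edgeR recovered 63.6% of 66 genes changed 1.5-fold and 86.6% of 67 changed 2-fold in bbx2021, with 9 false calls among the unchanged genes. Few genes were changed in that simulation, while 51.7% of the tested genes were called in smax1smxl2. It therefore does not test the scaling or the number of false calls in smax1smxl2. A length trend simulated in smax1smxl2 gave 525 false calls, and 15 with length offsets. That trend had the same slope in all smax1smxl2 libraries. It was shallower than the gap in the data, where the closest Col-0 and smax1smxl2 libraries lay 0.211 apart in log2 CPM per doubling of length. The 525 therefore does not bound the false calls that length could cause in the data. Gene Ontology terms of 10 to 500 genes were tested by the hypergeometric test, without and with length offsets, chosen after the data were seen.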

Results

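Transcript levels were measured by RNA-seq of polyadenylated RNA from whole Arabidopsis thaliana seedlings of 3 genotypes, with 3 libraries each: the wild type Col-0, the mutant line bbx2021 and the mutant line smax1smxl2. By its name, bbx2021 lacks the B-box factors BBX20 and BBX21, and smax1smxl2 lacks SMAX1 and SMXL2, the repressors that are degraded when karrikin signalling is active. Seeds were stratified for 2 days at 4 °C and seedlings grew for 4 days at 22 °C in red light of 80 µmol m-2 s-1. The libraries held between 22608018 and 25230110 gene counts and between 22601 and 22927 genes above 0. Of 24640 genes above 0 in at least 1 library, 20763 were tested. The biological coefficient of variation was 9.76%. The first principal component held 62.2% of the variance and separated smax1smxl2 from both other genotypes. On the second component, with 14.4%, smax1smxl2 replicate 1 (21.4) stood with the Col-0 libraries (18.8 to 22.9), and replicates 2 and 3 (-7.11 and -14.3) stood nearer the bbx2021 libraries (-33.0, -10.6 and -20.0).

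The mutated genes came first as a check of the labels. BBX21 (AT1G75540, chromosome 1, 28365824 to 28367738, TAIR10) stood at 127, 119 and 123 TMM-scaled CPM in the Col-0 libraries and at 40.3, 44.8 and 47.6 CPM in the bbx2021 libraries, a fall of 2.79-fold. BBX20 (AT4G39070, chromosome 4, 18204631 to 18206684) stood at 8.57, 8.67 and 7.69 CPM in Col-0 and at 6.67, 7.13 and 6.86 CPM in bbx2021, a log2 difference of -0.27 ± 0.09 (SE, n = 3 per group, edgeR adjusted p = 0.127) that did not pass the test. In smax1smxl2, BBX20 rose 3.71-fold to 32.1, 29.7 and 30.7 CPM and BBX21 fell to 90.2, 83.0 and 79.3 CPM. SMAX1 (AT5G57710) stood at 93.6, 90.4 and 84.0 CPM in Col-0, at 87.3, 86.9 and 90.9 CPM in bbx2021 and at 63.9, 68.5 and 63.4 CPM in smax1smxl2, a log2 change of -0.45 ± 0.07 in smax1smxl2 (adjusted p = 0.000212), which was no longer called with offsets for gene length. SMXL2 (AT4G30350) stood at 26.6, 26.6 and 23.1 CPM in Col-0, at 22.9, 24.2 and 27.1 CPM in bbx2021 and at 128, 126 and 142 CPM in smax1smxl2, a log2 change of 2.37 ± 0.09 (adjusted p = 2.2e-09). The position of each insertion or mutation is not given in the sources used here, so transcript level alone does not show loss of function.

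The comparison of bbx2021 with Col-0 asked which transcripts differ in the line named for the loss of BBX20 and BBX21. HY5 and HYH, the bZIP factors that promote photomorphogenesis, fell: HY5 from 10.5 ± 0.28 to 5.57 ± 0.35 CPM (SD, n = 3 per group), and HYH from 7.23 ± 0.30 to 3.48 ± 0.36 CPM. MYB12, an activator of flavonol genes, dropped from 4.16 ± 0.41 to 0.987 ± 0.11 CPM, and FLS1, which encodes flavonol synthase, from 21.3 ± 2.2 to 3.93 ± 0.15 CPM. AIR1, named for its auxin induction in root cultures, rose from 8.48 ± 0.32 to 33.3 ± 5.1 CPM, and TIP2;3, a tonoplast aquaporin of roots, from 37.8 ± 4.0 to 82.9 ± 7.4 CPM. In all, 425 genes were higher and 260 lower, of which 68 and 48 changed at least 2-fold.

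**Figure D1:**
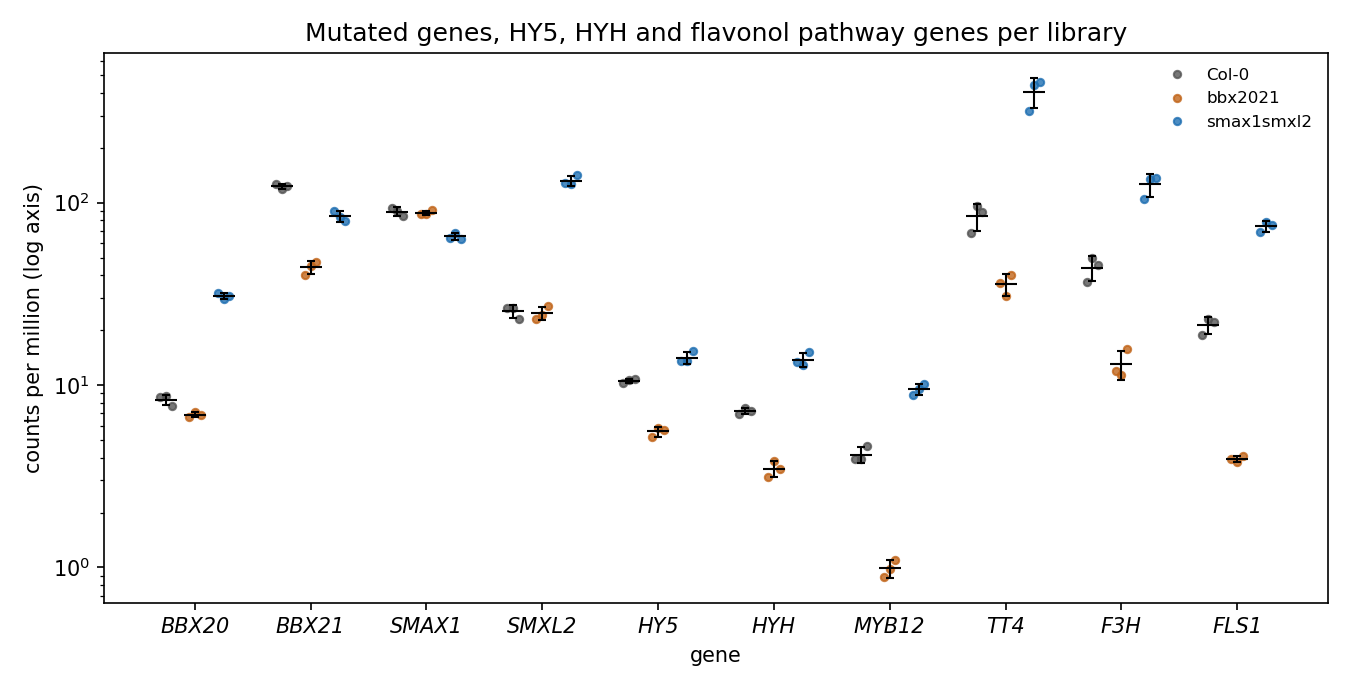
TMM-scaled CPM on a log axis for 10 genes in each of the 9 libraries, with points for libraries, horizontal marks for group means and bars for 1 SD (n = 3). HY5, HYH, MYB12, TT4, F3H and FLS1 were lowest in bbx2021 and highest in smax1smxl2.

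Among genes with a symbol, a mean of at least 50 counts in the group where they were higher, and libraries that do not overlap, the largest falls in bbx2021 were led by TTL4. It dropped by 3.17 on the log2 scale (SE 0.10, adjusted p = 8.41e-10), FLS1 by 2.44 (SE 0.11, adjusted p = 2.11e-08), MYB12 by 2.07 (SE 0.16, adjusted p = 7.77e-06), F3H, a flavanone hydroxylase, by 1.76 (SE 0.15, adjusted p = 6.04e-05), and the transporter gene ABCI21 and the beta-glucosidase gene BGLU19 fell 2.94-fold and 2.82-fold. The largest rises under the same limits were those of the nitrate transporter gene NRT1.8 (2.47 ± 0.32, adjusted p = 0.000978), the cytochrome P450 gene CYP710A4 (2.04 ± 0.28), AIR1 (1.97 ± 0.12), PXMT1 (1.89 ± 0.28), ENODL1 (1.59 ± 0.24) and PGL4 (1.48 ± 0.18). NRT1.8 overlaps CPL1 and BGLU19 overlaps AT3G21360, so their reads are uncertain.

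Of the 27 light signalling regulators, 4 fell in bbx2021, none rose and 23 did not pass the test: HYH (-1.05 ± 0.12), HY5 (-0.92 ± 0.10), RUP1, a repressor of UV-B signalling (-0.50 ± 0.12), and HFR1, a bHLH factor of light signalling (-0.42 ± 0.09). HFR1 lost its call when any 1 Col-0 or bbx2021 library was left out. RUP1 lost its call for any of these but bbx2021 replicate 1, and also without smax1smxl2 replicate 2. Adjusted over the list alone, 8 fell. The list passed the camera test as lower (adjusted p = 0.000704; adjusted p = 0.368 with an estimated correlation). Of the 22 flavonoid and anthocyanin enzyme genes, 5 fell and 4 rose, or 6 and 10 when adjusted over the list alone, and DESeq2 called 10 higher and 5 lower. The falls included FLS1, F3H, TT4 for chalcone synthase (-1.24 ± 0.16) and 4CL3 (-0.65 ± 0.16), and the rises included UF3GT, an anthocyanin glycosyltransferase (1.32 ± 0.27). 4CL3 lost its call when any 1 Col-0 or bbx2021 library but bbx2021 replicate 1 was left out, and also without smax1smxl2 replicate 2. UF3GT lost its call without replicate 1 or 2 of Col-0 or of bbx2021. The list's median was 0.12 and its mean 0.09, while camera placed it lower without a call (adjusted p = 0.203). The call came as lower without Col-0 replicate 1 (adjusted p = 0.02) or without bbx2021 replicate 1 (adjusted p = 0.0356), within a range of 0.02 to 0.901 over single libraries left out, and with length and GC offsets (adjusted p = 0.00553). Of the 10 tested flavonoid and anthocyanin regulators, only MYB12 fell and none rose (1 higher and 1 lower adjusted over the list alone; list lower, adjusted p = 0.0288, and adjusted p = 0.32 with an estimated correlation). That call ended without Col-0 replicate 2 (adjusted p = 0.0849) or bbx2021 replicate 1 (adjusted p = 0.0682), within a range of 0.0158 to 0.0849.

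For cell wall loosening genes all calls were rises. Of 15, 7 rose in bbx2021 and none fell (8 and 0 adjusted over the list alone), among them XTH33 (0.76 ± 0.11) and XTH19 (0.62 ± 0.10), which encode xyloglucan-modifying enzymes, and the expansin genes EXPA10 (0.51 ± 0.12) and EXPA1 (0.48 ± 0.11). EXPA10 lost the call when any 1 Col-0 or bbx2021 library was left out, and EXPA1 for any of these but bbx2021 replicate 2. Both also lost it with the replicate block and with the mitochondrial share as a covariate. The list was higher (median 0.38, adjusted p = 5.15e-08; adjusted p = 0.222 with an estimated correlation). Of the 10 root markers, TIP2;3 (1.13 ± 0.11) and the Casparian strip genes CASP2 (0.43 ± 0.11) and CASP1 (0.39 ± 0.09) rose and none fell (3 higher and 1 lower adjusted over the list alone; list adjusted p = 0.015, and adjusted p = 0.32 with an estimated correlation). CASP1 and CASP2 lost their calls in 12 of 23 alternative settings each. Of the 12 root hair markers none was called (0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.721, median 0.14, mean -0.03). The 2 most abundant, PRP3 and PRP1, stood at 0.24 ± 0.16 and 0.14 ± 0.14.

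Chlorophyll synthesis genes PORA (1.27 ± 0.23) and PORB (0.42 ± 0.09), which encode protochlorophyllide oxidoreductases, rose, and none of the 18 on the list fell (6 and 0 adjusted over the list alone; list higher, adjusted p = 1.78e-05, and adjusted p = 0.339 with an estimated correlation). PORA lost the call without replicate 2 or 3 of Col-0 or of bbx2021, and PORB without any of these or bbx2021 replicate 1. None of the 35 photosystem, antenna and Rubisco genes was called on either scale. LHCB1.3 and LHCB1.5, antenna genes with near-identical or overlapping genes, stood at 0.22 ± 0.12 and 0.10 ± 0.12. The list passed camera as higher (median 0.11, adjusted p = 0.00485; adjusted p = 0.726 with an estimated correlation), but not with fry (adjusted p = 0.352) or with length and GC offsets (adjusted p = 0.494). It did not pass without bbx2021 replicate 1 either (adjusted p = 0.156, range over single libraries left out 0.00109 to 0.156), the library with the highest chloroplast share in its group (0.961% against 0.550% and 0.682%), and its median was -0.11 with the mitochondrial share as a covariate. Of the 15 gibberellin genes, GA20OX1 (0.74 ± 0.15) and GA3OX1 (0.60 ± 0.09) rose and GA3OX2 (-1.07 ± 0.19) fell, all for synthesis enzymes (4 higher and 2 lower adjusted over the list alone; list higher, adjusted p = 0.00498, and adjusted p = 0.368 with an estimated correlation). GA20OX1 lost its call without some single libraries. Of the 19 ethylene genes, 2 rose, among them ACS5 (0.73 ± 0.12), which encodes a synthesis enzyme, and none fell (2 and 0 adjusted over the list alone; list higher, adjusted p = 0.0461, and adjusted p = 0.339 with an estimated correlation). The ethylene list lost its call without Col-0 replicate 2 (adjusted p = 0.117) or 3 (0.122), bbx2021 replicate 1 (0.0666) or 3 (0.0776), and smax1smxl2 replicate 1 (0.0534) or 3 (0.0551), and with the replicate block (0.0617), and its median was -0.02 with limma on FPKM.

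The remaining lists did not pass camera in bbx2021. Of 14 brassinosteroid genes, PRE1 (1.00 ± 0.15) and PRE6 (0.63 ± 0.09), which encode growth-promoting bHLH proteins, rose and none fell (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.0608). The list was called as higher with length offsets (adjusted p = 0.043), with length and GC offsets (0.0163), and without Col-0 replicate 1 (0.00115) or bbx2021 replicate 1 (0.0407), within a range of 0.00115 to 0.233 over single libraries left out. Of 12 clock genes only ELF4 fell (-0.42 ± 0.10; 0 higher and 2 lower adjusted over the list alone, adjusted p = 0.077). The clock list was called as lower with length and GC offsets (adjusted p = 0.0327) and without Col-0 replicate 1 (adjusted p = 0.0466), bbx2021 replicate 3 (0.0311) or smax1smxl2 replicate 1 (0.04), within a range of 0.0311 to 0.197. Of 20 tested other BBX genes only BBX25 rose (0.43 ± 0.08; 1 and 0 adjusted over the list alone, adjusted p = 0.659). BBX25, with a mean of 745 counts, overlaps AT2G31390, with a mean of 3030, so its reads are uncertain. Of the 8 tested genes of the jasmonate and salicylate list, all jasmonate genes, only VSP1 rose (0.56 ± 0.13; 1 and 0 adjusted over the list alone, adjusted p = 0.232). VSP1 lost its call in 11 of 23 alternatives, ELF4 in 6 and BBX25 in 4. No gene was called among 8 tested karrikin and strigolactone genes (DLK2 0.38 ± 0.12 and KAI2 -0.24 ± 0.08; 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.721), 28 auxin genes (PIN3 0.19 ± 0.11 and PIN7 -0.04 ± 0.09; 0 and 0 adjusted over the list alone, adjusted p = 0.594) or 12 heat and cold genes (RD29A 0.18 ± 0.30 and HSP70-4 0.62 ± 0.19; 0 and 0 adjusted over the list alone, adjusted p = 0.459). The same held for 12 stomatal lineage markers (SCRM -0.01 ± 0.08 and TMM 0.24 ± 0.09; 0 higher and 1 lower adjusted over the list alone, adjusted p = 0.232) and 11 seed storage markers (CRA1 -0.38 ± 0.63 and OLEO2 0.63 ± 0.21; 0 and 0 adjusted over the list alone, adjusted p = 0.077). The seed storage list, with a median of 0.98, was called as higher with the replicate block (adjusted p = 0.00904) and without Col-0 replicate 3 (0.00481), bbx2021 replicate 1 (0.0017) or bbx2021 replicate 2 (0.0221), within a range of 0.0017 to 0.499.

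The 685 calls in bbx2021 depended on the libraries in the fit. They numbered 316, 293 and 235 without Col-0 replicates 1, 2 and 3, 313, 383 and 311 without bbx2021 replicates 1, 2 and 3, and 1790 without smax1smxl2 replicate 1, a library of neither group compared. With only the 6 libraries compared 1381 genes were called, with DESeq2 1134, with limma on FPKM 443 (208 higher, 46.9% of them, against 62.0% of the 685), and with the mitochondrial share of the libraries as a covariate 271. Of 49 named genes called in bbx2021, 24 kept their call in all alternative fits, at the same threshold, HY5, HYH, MYB12, FLS1, F3H, TT4, TTL4, AIR1, TIP2;3 and XTH33 among them, and 19 lost it without at least 1 single library. CYP710A4, PXMT1, ENODL1 and WRKY70 lost it only with the mitochondrial share as a covariate. That share was higher in every bbx2021 library than in Col-0, so such a loss cannot be told apart from the genotype.

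The comparison of smax1smxl2 with Col-0 asked which transcripts differ in the line named for the loss of the karrikin signalling repressors. DLK2, a transcriptional marker of karrikin signalling, rose 62.1-fold from 7.42 ± 0.30 to 461 ± 38 CPM (SD, n = 3 per group), and the karrikin-upregulated F-box gene KUF1 rose 4.36-fold from 11.2 ± 0.86 to 48.7 ± 4.5 CPM. All 35 photosystem, antenna and Rubisco genes rose, and 34 with the mitochondrial share as a covariate. MYB12 rose to 9.50 ± 0.67 CPM, FLS1 to 74.1 ± 5.0 CPM, HYH to 13.8 ± 1.2 CPM and HY5 to 14.1 ± 1.0 CPM, the last without a call with length offsets, and all 4 fell in bbx2021. Auxin, brassinosteroid, ethylene and jasmonate genes fell more often than they rose, as did wall loosening genes. In all, 5088 genes were higher and 5639 lower, 51.7% of those tested, and 745 and 774 of them changed at least 2-fold.

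Apart from DLK2, which has no symbol in the files and is named through its list, the 6 largest rises in smax1smxl2 under the naming rule were MRD1 (7.67 ± 0.33, adjusted p = 3.07e-08), the seed storage albumin genes SESA2 (5.25 ± 1.19, adjusted p = 0.0105) and SESA1 (4.79 ± 1.07, adjusted p = 0.00704), the chloroplast gene PSBA of photosystem II (3.72 ± 0.81, adjusted p = 0.00954), LCR67 (3.70 ± 0.66) and the light-stress gene ELIP2 (3.68 ± 0.20, adjusted p = 2.47e-08). MRD1 overlaps HEI10, so its reads are uncertain, and the SESA2 level of 10.3 ± 9.2 CPM varied widely between libraries. PSBA varied too, at 114, 408 and 582 CPM in smax1smxl2, and bbx2021 replicate 1 (194 CPM) stood above the lowest of these. RNA was selected with oligo(dT), and how much chloroplast RNA this kept in each library was not measured. The naming rule needs a symbol, a mean of at least 50 counts in the group where the gene is higher, and libraries that do not overlap. The 6 largest falls under it included triterpene genes: MRN1 for marneral synthase dropped by 5.20 (SE 0.22, adjusted p = 2.26e-08), and CYP716A2 (-4.54 ± 0.19, adjusted p = 4.44e-09), PEN3 (AT5G36150), a putative triterpene synthase gene (-3.60 ± 0.15), and CYP705A12 fell too. MLP31 (-4.73 ± 0.38) and CWINV5 (-3.19 ± 0.74), which overlaps NAP1;4, were the others.

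Of 8 tested karrikin and strigolactone genes, 4 rose and 3 fell, with the same counts adjusted over the list alone. With length offsets 4 rose and none fell. DLK2, KUF1 (2.12 ± 0.10), the karrikin receptor gene KAI2 (0.52 ± 0.08) and the strigolactone receptor gene D14 (0.43 ± 0.09) rose, and the list was higher (adjusted p = 1.05e-06; adjusted p = 0.0871 with an estimated correlation). D14 lost its call with limma on FPKM. Rubisco small subunit genes RBCS1B (1.56 ± 0.16), RBCS3B (1.52 ± 0.15), RBCS1A and RBCS2B (1.29 ± 0.15) rose most of the photosystem, antenna and Rubisco list, all 35 also adjusted over the list alone (median 0.90, adjusted p = 3.45e-27; adjusted p = 0.32 with an estimated correlation). Chloroplast transcripts made 0.963% to 1.2% of the smax1smxl2 counts and 0.548% to 0.639% of the Col-0 counts, and the 10 most abundant genes 11.7% to 13.0% against 7.76% to 8.02%. The chloroplast shares are those of oligo(dT)-selected RNA and need not follow the levels in the seedlings. Of 18 chlorophyll synthesis genes 13 rose and 1 fell, with the same counts adjusted over the list alone, among them DVR (0.85 ± 0.09), the chloroplast development regulator GLK1 (0.78 ± 0.09), CHLI1 (0.72 ± 0.10) and CHLM (0.65 ± 0.09; list adjusted p = 0.000324, and adjusted p = 0.376 with an estimated correlation).

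Of the 22 flavonoid and anthocyanin enzyme genes 10 rose and 4 fell in smax1smxl2, with the same counts adjusted over the list alone. TT4 (2.27 ± 0.16), TT7, a flavonoid hydroxylase (2.27 ± 0.14), 4CL3 (2.07 ± 0.14) and FLS1 (1.80 ± 0.09) led the rises (median 0.05, list higher, adjusted p = 0.000704; adjusted p = 0.449 with an estimated correlation). Of 10 tested regulators, MYB12 (1.19 ± 0.12), MYBL2 (0.75 ± 0.11) and TTG1 (0.22 ± 0.09) rose and MYB75, an activator of anthocyanin genes, fell (-1.55 ± 0.27; 2 higher and 1 lower adjusted over the list alone, list adjusted p = 0.437). TTG1 lost its call in 15 of 23 alternatives and turned to the other sign with limma on FPKM, and MYB75 lost it with the mitochondrial share as a covariate. With limma on FPKM the medians were -0.14 for the enzyme genes and -0.04 for the regulators, of which 2 rose and 2 fell. Of 27 light signalling regulators 17 fell and 5 rose, with the same counts adjusted over the list alone. ELIP2 and HYH (0.93 ± 0.11) rose, and PIF3 (-0.79 ± 0.14), which promotes growth in darkness, and HFR1 (-0.77 ± 0.10) fell. The median was -0.34, the mean -0.05, and the list did not pass (adjusted p = 0.231), though it did as lower with fry (adjusted p = 0.0391). With length offsets 9 of these regulators fell and 5 rose, with a median of -0.12 (camera adjusted p = 0.928). HY5 (0.42 ± 0.09) and RUP1 (0.49 ± 0.12) rose, and both lost the call with limma on FPKM. With length offsets HY5 was at 0.10 without a call (adjusted p = 0.382), and HYH dropped to 0.33 (adjusted p = 0.0265).

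The auxin, brassinosteroid, ethylene and jasmonate and salicylate lists passed camera as lower in smax1smxl2. The last of these held no tested salicylate gene. The gibberellin list did not pass. Of 28 auxin genes 18 fell and 3 rose, 20 and 3 adjusted over the list alone, led by IAA6 (-2.80 ± 0.25), SAUR15 (-1.55 ± 0.31), IAA19 (-1.53 ± 0.12) and the synthesis gene YUC2 (-1.28 ± 0.17; list median -0.68, adjusted p = 5.34e-05, and adjusted p = 0.32 with an estimated correlation). Of 14 brassinosteroid genes 10 fell and PRE1 (0.68 ± 0.15) rose, or 11 and 1 adjusted over the list alone, with PRE5 (-1.72 ± 0.57), the synthesis gene BR6OX1 (-1.61 ± 0.13) and PRE6 (-0.67 ± 0.09) among the falls (list adjusted p = 0.00317, and adjusted p = 0.369 with an estimated correlation). PRE5 lost its call without Col-0 replicate 1 or smax1smxl2 replicate 1, and PRE1 with length offsets. Of 19 ethylene genes 13 fell and 3 rose, or 14 and 3 adjusted over the list alone, and the ACC synthase genes ACS4 (-3.78 ± 0.56), ACS8 (-3.04 ± 0.34), ACS5 (-2.53 ± 0.16) and ACS2 (-1.12 ± 0.20) led (list adjusted p = 0.000565, and adjusted p = 0.317 with an estimated correlation). Of its 8 tested genes, all jasmonate genes, 5 fell and none rose on either scale for the jasmonate and salicylate list (list adjusted p = 0.0016, and adjusted p = 0.32 with an estimated correlation). VSP1 (-2.46 ± 0.15), VSP2 (-1.23 ± 0.19), MYC2, the jasmonate bHLH factor (-1.41 ± 0.11), and JAZ5 (-1.27 ± 0.42) were among them. JAZ5 lost its call in 7 of 20 alternatives, and MYC2 overlaps AT1G32630. Of 15 gibberellin genes 3 rose and 4 fell, with the same counts adjusted over the list alone (median 0.05, mean -0.10, adjusted p = 0.857), among them GA20OX1 (-1.35 ± 0.19), GA2OX1 (-0.98 ± 0.34), GA2OX2 (0.62 ± 0.14) and GA3OX2 (0.60 ± 0.17). GA2OX1 and GA3OX2 lost their calls in 6 alternatives each, and the list split into 3 higher and 2 lower with DESeq2, 1 and 7 with limma on FPKM, and 6 and 4 with length offsets.

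Of 15 wall loosening genes 9 fell and 3 rose, with the same counts adjusted over the list alone. XTH17 (-2.25 ± 0.13), XTH33 (-1.52 ± 0.13), EXPA8 and EXPA11 (-1.09 ± 0.09) fell most (list adjusted p = 0.00042, and adjusted p = 0.32 with an estimated correlation). Of 12 clock genes 6 fell and 3 rose, or 7 and 3 adjusted over the list alone (list adjusted p = 0.232, and 0.0297 as lower with fry), with PRR7 (-0.82 ± 0.19), ELF3 (-0.82 ± 0.12) and RVE8 (-0.66 ± 0.09) lower and ELF4 higher (0.63 ± 0.09). With length offsets 4 clock genes fell and 1 rose (list median -0.095), and ELF4 turned to the other sign. Of 12 heat and cold genes 4 rose and 1 fell, or 3 and 1 adjusted over the list alone (list adjusted p = 0.437), with the cold regulators DREB1B (2.15 ± 0.33), DREB1A (0.97 ± 0.28) and DREB1C (0.66 ± 0.26) and their target COR15A higher. DREB1C lost its call in 16 of 22 alternatives, COR15A lost it with length offsets, and with limma on FPKM 1 gene of the list was higher and 3 were lower. Of 20 tested other BBX genes 5 rose and 2 fell, or 4 and 2 adjusted over the list alone (list adjusted p = 0.594), with BBX30 (0.76 ± 0.23) and BBX25 (0.43 ± 0.08) higher and BBX16 (-0.54 ± 0.12) and BBX27 (-0.53 ± 0.12) lower. BBX30 lost its call in 6 of 22 alternatives, and BBX25 with limma on FPKM, where 1 gene of the list was higher and 6 were lower. The reads of BBX25, which overlaps AT2G31390, are uncertain.

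None of the 4 lists of cell type and tissue markers passed camera in smax1smxl2, where 51.7% of all tested genes were called. With length and GC offsets root hair markers passed as lower (adjusted p = 0.00821) and stomatal lineage markers as higher (0.0444), and with fry root markers passed as lower (0.00535) and stomatal lineage markers as higher (0.00245). Fry does not compare a list with other genes. With so many genes called, passing it does not show a shift particular to these markers. Of 12 stomatal lineage markers 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (list adjusted p = 0.0826). The patterning genes EPF2 (1.11 ± 0.18) and EPF1 (0.96 ± 0.22) and the lineage regulator MUTE (0.94 ± 0.28) rose, and the guard cell channel gene KAT1 fell (-0.88 ± 0.12). With length offsets EPF1 (0.49, adjusted p = 0.0545) and MUTE (0.55, adjusted p = 0.137) lost their calls, and MUTE also without Col-0 replicate 3. Of 10 root markers TIP2;3 (-1.05 ± 0.11), PYK10 (-0.50 ± 0.10) and PHO1 (-0.41 ± 0.09) fell and none rose, also adjusted over the list alone (list adjusted p = 0.231), and of 12 root hair markers RSL2 (-0.55 ± 0.19), COBL9 (-0.54 ± 0.10) and PRP1 (-0.53 ± 0.14) fell and none rose (2 lower adjusted over the list alone, list adjusted p = 0.2). PHO1 lost its call with length offsets, RSL2 without Col-0 replicate 1 or 2 or smax1smxl2 replicate 2, and PYK10 overlaps AT3G09250. Of 11 seed storage markers 5 rose and none fell on either scale (median 1.28, list adjusted p = 0.224), SESA2, SESA1, CRB (AT1G03880, 3.62 ± 1.26) and SESA3 (2.86 ± 0.93) among them. CRB and SESA3 lost their calls without several single libraries, and ran from 3.073 to 7.32 and from 2.221 to 5.005 over single libraries left out. In Col-0, SESA1 stood at 0.073 to 0.146 CPM and CRB at 0 to 0.182 CPM. The most abundant of the list, CRA1 and OLEO2, did not rise. CRA1 stood at 279, 312 and 390 CPM in Col-0 and at 123, 301 and 71.1 CPM in smax1smxl2. OLEO2 stood at 84.4, 101 and 100 CPM in Col-0 and at 81.9, 88.8 and 99.7 CPM in smax1smxl2.

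**Figure D2:**
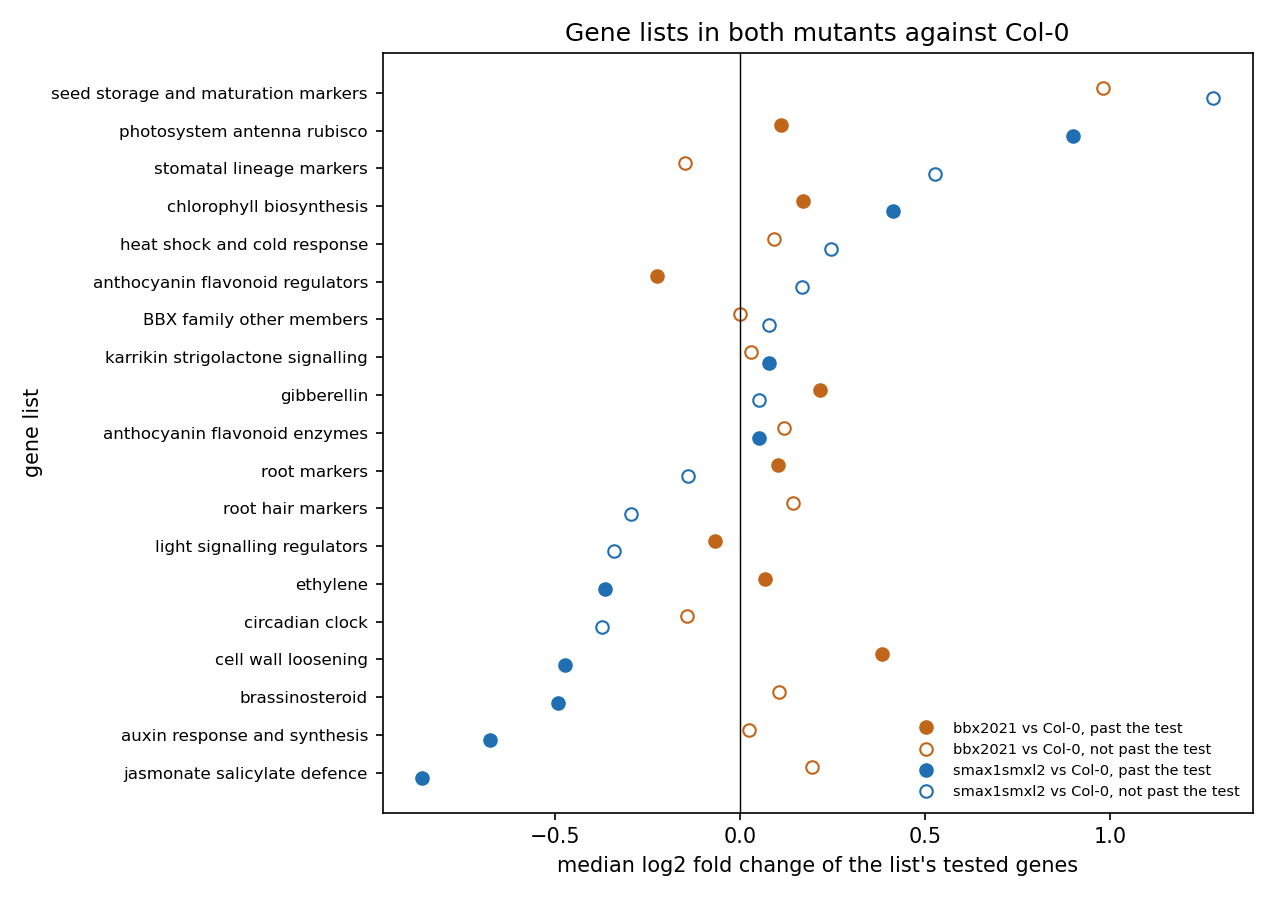
Median log2 fold change of the tested genes of each list in bbx2021 and in smax1smxl2 against Col-0, with filled points for lists that passed camera with a preset correlation and open points for the others (none passed with an estimated correlation). Cell wall loosening had a median of 0.38 in bbx2021 and of -0.47 in smax1smxl2.

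Fold changes in smax1smxl2 fell with gene length. The median log2 fold change was 0.54 in the tenth of the genes with the shortest models and -0.38 in the tenth with the longest, and Spearman's rho across 20763 genes, which are not independent replicates, was -0.464. In bbx2021 it was -0.175. With offsets for gene length and GC content, chosen after the data were seen, 8631 genes were called in smax1smxl2, and 6640 of the 10727 calls (61.9%) remained in the same direction. With limma on FPKM the calls split into 2476 higher and 9486 lower (20.7% higher, against 47.4%), and the median log2 fold change of all genes lay at -0.25 instead of -0.03. The FPKM values were used without TMM factors, which were 1.084 to 1.091 in Col-0 and 0.8555 to 0.981 in smax1smxl2. This shift may therefore reflect scaling. With the mitochondrial share as a covariate 5279 genes were called, and SESA2, SESA1, LCR67, CWINV5, D14, PIF3, RUP1, SAUR15, GA2OX2, PRR7, DREB1A, EPF1, BBX16 and BBX27 were among the named genes that lost the call. The share was higher in every smax1smxl2 library than in Col-0, so these losses cannot be told apart from the genotype. Of 115 named genes called in smax1smxl2, 76 kept the call in all alternative fits at the same threshold, and 12 lost it without at least 1 single library.

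**Figure D3:**
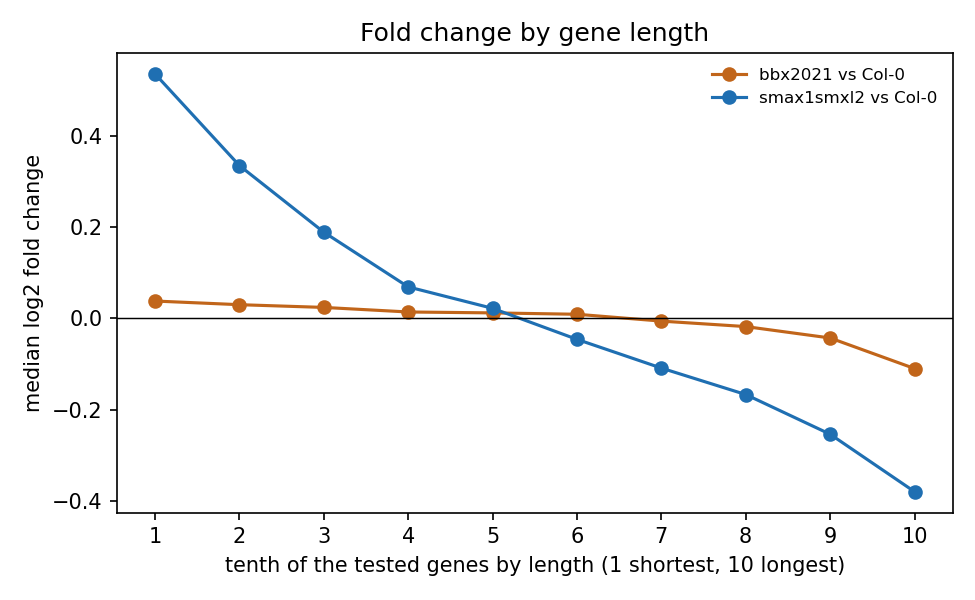
Median log2 fold change against Col-0 (vertical axis) in 10 groups of tested genes ordered by gene length (horizontal axis), for both mutants. In smax1smxl2 the medians ran from 0.54 in the shortest group to -0.38 in the longest, and in bbx2021 from 0.04 to -0.11.

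The comparison of both mutants' changes asked whether the genes that differ in bbx2021 are those that differ in smax1smxl2. HY5, HYH, MYB12, the flavonoid genes FLS1, F3H (1.52 ± 0.14 in smax1smxl2) and TT4, and the transporter gene ABCI21 (0.77 ± 0.09) were lower in bbx2021 and higher in smax1smxl2. HY5 lost its call in smax1smxl2 with length offsets and with limma on FPKM. AIR1 (-2.70 ± 0.16 in smax1smxl2), MRN1 (1.47 ± 0.15 in bbx2021), CYP710A4 (-4.05 ± 0.58), PGL4 (-1.32 ± 0.23), TIP2;3 and EXPA8 (0.47 ± 0.09 in bbx2021) were higher in bbx2021 and lower in smax1smxl2. EXPA8 lost its call in bbx2021 without Col-0 replicate 2 or 3 and with the mitochondrial share as a covariate. WRKY70 (1.42 ± 0.21 and 1.26 ± 0.21), the peroxidase gene PRXCB (1.01 ± 0.11 and 0.88 ± 0.11) and the extensin gene EXT4 (0.82 ± 0.12 and 1.51 ± 0.12) rose in both mutants, and the beta-glucosidase genes BGLU19 (-1.03 ± 0.11 in smax1smxl2) and BGLU28 (-1.10 ± 0.16 and -1.86 ± 0.17) fell in both. Of 437 genes called in both mutants, 276 went in opposite directions and 161 in the same one. Of the opposite ones, 202 were higher in bbx2021 and lower in smax1smxl2, and 74 the reverse, against 115 and 63.7 for independent lists. Of the same-direction ones, 64 were higher and 97 lower in both mutants, against 104 and 70.6. Independent lists of these sizes would share 179 genes in opposite and 175 in the same directions. Simulated unchanged groups against the same Col-0 libraries shared 0 in 10 simulations. No gene was changed in them, so a number near 0 was set in advance. They do not show what shared controls do to lists of these sizes.

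**Figure D4:**
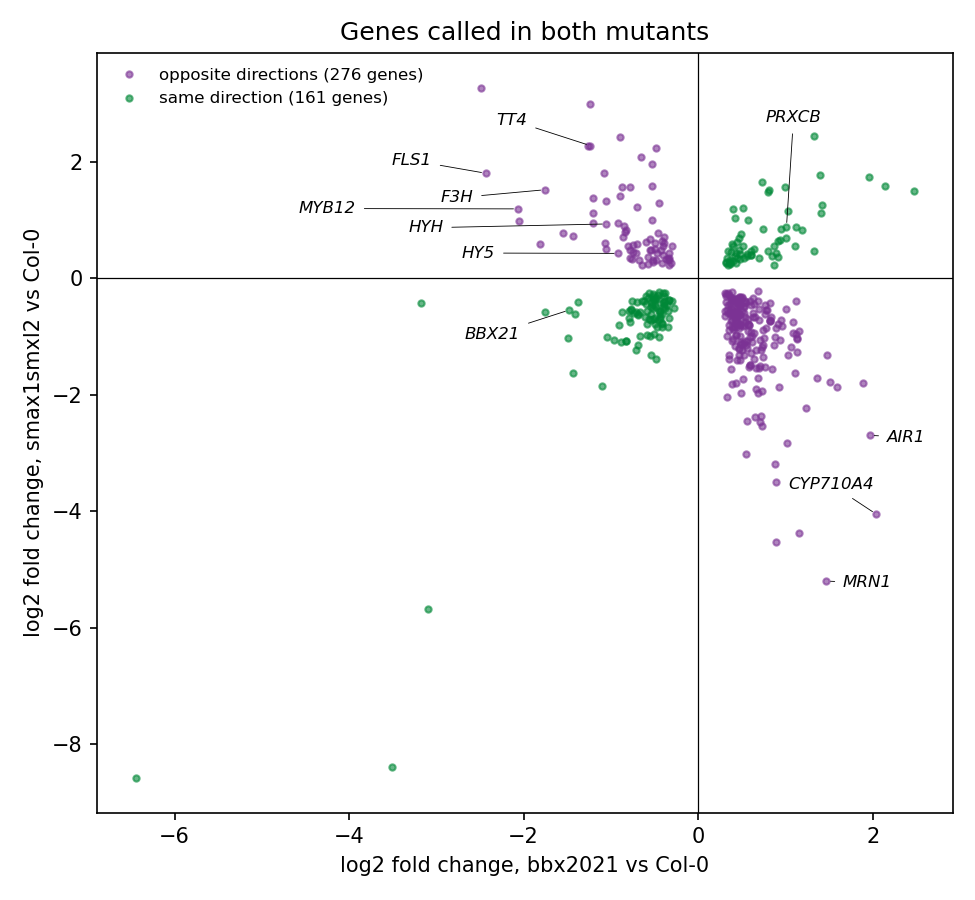
Log2 fold change in bbx2021 (horizontal axis) and in smax1smxl2 (vertical axis), both against Col-0, for the 437 genes called in both, with purple points for the 276 that went in opposite directions and green points for the 161 that went in the same one. The 3 green points at the lower left are genes near 0 counts in smax1smxl2, whose fitted fold changes depend on the prior count.

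The excess of opposite calls depended on the libraries and groups in the fit. Without smax1smxl2 replicate 1, opposite calls numbered 440, below the 499 of independent lists, and same-direction calls 746, above 495. At 2-fold or more, again without that library, there were 30 and 54, against 8.45 and 8.88 for independent lists. Without Col-0 replicates 1, 2 and 3 the opposite calls were 144, 129 and 93 and the same-direction calls 73, 54 and 54, and without bbx2021 replicates 1, 2 and 3 they were 144, 147 and 145 against 62, 97 and 66. With only the groups compared in each fit there were 382 opposite and 434 same-direction calls, against 345 and 344 for independent lists. With length and GC offsets but not smax1smxl2 replicate 1 there were 489 and 526, against 379 and 372 for independent lists. At 2-fold or more with all libraries, 28 genes went in opposite directions and 15 in the same, against 4.26 and 4.23 for independent lists. Across all 20763 tested genes Pearson's r between the mutants' log2 fold changes was 0.068 and Spearman's rho 0.154, and genes are not independent replicates. Pearson's r was 0.136, 0.115 and 0.169 without Col-0 replicates 1, 2 and 3, 0.038 and 0.127 without bbx2021 replicates 1 and 2, and 0.126 without smax1smxl2 replicate 1, and with no filter on low counts it was 0.279 and with the mitochondrial share as a covariate -0.05. The covariance was 0.0157, against 0.0187 in simulated unchanged groups that share the controls, a difference of -0.003. Pearson's r averaged 0.486 in those simulated groups, which hold no changed gene, so shared controls alone do not give an r of 0.

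The direct comparison of smax1smxl2 with bbx2021 uses no Col-0 library in the contrast. FLS1 was 18.8-fold higher in smax1smxl2 than in bbx2021 (log2 4.24 ± 0.11, adjusted p = 1.15e-11) and F3H 9.67-fold higher (3.27 ± 0.16, adjusted p = 1.32e-08), while MRN1 dropped by 6.67 on the log2 scale (SE 0.22, adjusted p = 1.77e-09), and CYP710A4 (-6.09 ± 0.47), CYP716A2 (-5.42 ± 0.18) and AIR1 (-4.67 ± 0.15) were lower as well. ATS3, an embryo-specific gene, was higher (5.76 ± 0.34, adjusted p = 2.72e-08), as was MRD1 (8.38 ± 0.36). DIR1 had 0 counts in bbx2021 and was at least 358-fold higher in smax1smxl2 (floor of 3 counts over the group), but it overlaps AT5G48480 and its reads are uncertain. BBX20 (2.16 ± 0.09) and SMXL2 (2.41 ± 0.09) were higher in smax1smxl2, as was BBX21 (0.93 ± 0.08), and SMAX1 was lower (-0.44 ± 0.07). In all, 5091 genes were higher and 5334 lower in smax1smxl2 than in bbx2021, 759 and 1030 of them at least 2-fold. With limma on FPKM the split was 3025 higher and 7312 lower (29.3% higher, against 48.8%), with a median of all genes at -0.16. Of 17 named calls, 14 remained in all alternative fits at the same threshold, and SMAX1 lost its call with length offsets.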

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

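The offsets for gene length and GC content and the mitochondrial covariate were chosen after the results were seen, and the other settings were fixed before. The calls in smax1smxl2 against Col-0 and against bbx2021 stayed within 1.5 times of 10727 and 10425 in all alternatives but the mitochondrial covariate (5279 against Col-0) and a minimum of 2-fold (1519 and 1789). Leaving out single libraries moved the 685 calls in bbx2021 to between 235 and 1790, and the calls in both mutants to between 93 and 440 opposite and between 54 and 746 in the same direction. The correlation of fold changes moved to between 0.038 and 0.169. Of 198 gene results, 120 kept their direction and their side of the threshold in all alternative fits, 66 lost a call without a change of sign in at least 1, 3 gained a call and 11 changed sign. The stricter thresholds were applied to the counts of genes and not to single genes. The causes were not tested. Counts of genes, with 685 calls in bbx2021, 276 opposite and 161 same-direction calls as the starting values, moved as follows. DESeq2 called 1134 genes in bbx2021 and 290 in the same direction. It called 399 in opposite directions, within 1.5 times of the main value. A fit of only the groups compared gave 1381 and 434. With the replicate block 396 genes were called in bbx2021, 175 in opposite and 84 in the same direction, and 9958 and 9723 in smax1smxl2 against Col-0 and bbx2021. With limma on log2 FPKM plus 1, plus 0.1, and plus 1 without a filter, bbx2021 had 443, 377 and 323 calls, the opposite calls were 195, 175 and 139 and the same-direction calls 114, 89 and 74. With length and GC offsets but not smax1smxl2 replicate 1 they were 1692, 489 and 526. With the mitochondrial covariate they were 271, 124 and 31, and the correlation of fold changes, 0.068 at first, was -0.05. Without a filter on low counts that correlation was 0.279. At an adjusted p under 0.01 the calls in bbx2021 were 187, the opposite ones 84 and the same-direction ones 33, and at 2-fold or more 116, 28 and 15. With an estimated correlation 0 lists in bbx2021 and 0 in smax1smxl2 passed camera, of 8 and 9 at first.

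In bbx2021, SCRM (-0.01) was 0 with DESeq2 and with its size factors. With length offsets SMAX1 was at 0.095, SMXL2 at 0.056 and PIN7 at 0.003. With length and GC offsets SMAX1 was at 0.03, SMXL2 at 0.022, LHCB1.5 at -0.137, PIN7 at 0.036 and SCRM at 0.033, and without smax1smxl2 replicate 1 as well they were at 0.03, 0.022, -0.127, 0.035 and 0.031. With the mitochondrial covariate LHCB1.5 was at -0.089, PRP3 at -0.099 and PRP1 at -0.157. Over single libraries left out SMAX1 ran from -0.058 to 0.018, SMXL2 from -0.11 to 0.012, PIN7 from -0.104 to 0.042, SCRM from -0.065 to 0.025 and RD29A from -0.121 to 0.381. In smax1smxl2, TMM (0.22), called at first, was at -0.048, -0.052 and -0.048 in the 3 limma settings, and TTG1 (0.22), also called at first, at -0.062, -0.064 and -0.062, and at -0.018 with the mitochondrial covariate. ELF4 (0.63), called at first, was at -0.042 with length offsets, at -0.01 with length and GC offsets and at -0.043 with those but not smax1smxl2 replicate 1. Lists without a call whose camera direction turned were gibberellin in smax1smxl2 (adjusted p = 0.655 with length and 0.762 with length and GC offsets) and root hair markers in bbx2021 (0.731 with length and GC offsets, 0.369 to 0.828 over single libraries left out). In bbx2021 the direction also turned for heat and cold (0.191 to 0.968), auxin (0.131 to 0.972), karrikin and strigolactone (0.474 to 0.967) and other BBX genes (0.376 to 0.951) without single libraries. Fry differed from camera in 5 lists: photosystem, antenna and Rubisco genes in bbx2021 lost the call (adjusted p = 0.352), and in smax1smxl2 light signalling regulators (0.0391), clock genes (0.0297), root markers (0.00535) and stomatal lineage markers (0.00245) gained it. Fry does not compare a list with other genes, so a call gained with it answers a different question. Camera was not run with the mitochondrial covariate or with length and GC offsets without smax1smxl2 replicate 1.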

Other observations

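The Gene Ontology tests, and the tests of gene length as the whole cause of the calls, of the shared Col-0 libraries, of length and GC content in the overlap, of 1 library, of organelle transcripts, of copies and of linkage, were chosen after the results were seen. Among the 467 annotated genes at least 2-fold higher in smax1smxl2 than in Col-0, translation genes numbered 61 against 12.4 by chance (hypergeometric adjusted p = 2.69e-22 over 2892 term tests), photosynthesis genes 35 against 4.3 (adjusted p = 1.58e-19), genes annotated as responding to karrikin 25 against 4.02 (adjusted p = 1.33e-10), and genes of the reductive pentose-phosphate cycle 7 against 0.67 (adjusted p = 0.000593). Among the 508 at least 2-fold lower, glucosinolate synthesis genes numbered 11 against 0.959 (adjusted p = 4.69e-07), genes responding to auxin 28 against 9.01 (adjusted p = 3.55e-05) and terpenoid synthesis genes 7 against 0.537 (adjusted p = 9.2e-05). With length offsets the excess of translation genes (4 against 5.77, adjusted p = 1) and photosynthesis genes (6 against 2, adjusted p = 0.654) among the 217 higher genes was not called. These tests count only genes at least 2-fold higher. Without that minimum, all 35 photosystem, antenna and Rubisco genes stayed called as higher with length offsets. The median of that list was then 0.67 (camera with the preset correlation, adjusted p = 1.16e-24). Genes responding to karrikin (15 against 1.87, adjusted p = 7.3e-07) and of the pentose-phosphate cycle (4 against 0.311, adjusted p = 0.0341) remained in excess, the latter not with length and GC offsets (adjusted p = 0.0505). Among the 575 lower genes those of glucosinolate synthesis (9 against 1.09, adjusted p = 0.000407), auxin response (42 against 10.2, adjusted p = 9.05e-12) and terpenoid synthesis (6 against 0.608, adjusted p = 0.00467) did as well.

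Among the 30 annotated genes at least 2-fold lower in bbx2021, 5 are annotated as responding to karrikin, against 0.258 by chance (hypergeometric adjusted p = 0.00107), and 4 as responding to UV-B, against 0.122 (adjusted p = 0.0012). Among the 48 at least 2-fold higher, 3 belong to anthocyanin synthesis, against 0.058 (adjusted p = 0.00412). The call count of bbx2021 with only its 6 libraries was 1381, and the highest of the other splits of these libraries gave 1, with 1 of 10 splits as large as the real one. For smax1smxl2 the real split gave 10345 against Col-0 and 9493 against bbx2021, and the highest other split 0 in each, with 1 of 10 splits as large. For all 3 comparisons 10 splits are too few for a share under 0.05.

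Fold changes in smax1smxl2 fell with gene length. Outside genes annotated to the plastid or to ribosomes, 18015 genes, Spearman's rho was still -0.429, which argues against these short and abundant genes as the whole source. Of 10727 calls 6640 remained in the same direction with length and GC offsets, which argues against length bias as the whole cause of the calls. Length bias that varies between libraries cannot be told apart from the genotype, since the gap of 0.211 between the lowest Col-0 and the highest smax1smxl2 slope was no larger than the largest range within a group, 0.211. A change in the transcripts of short genes that comes with the genotype stays open as well.

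Genes called in both mutants went in opposite directions more often than independent lists would, 276 against 179. With only the groups compared in each fit the excess was smaller, 382 against 345. Shared Col-0 libraries would raise same-direction calls instead, so the 276 argue against them. With length and GC offsets there were 391 opposite calls (207 for independent lists), and with the mitochondrial covariate 124 (34.6). Fold changes fell with length in both mutants (Spearman's rho -0.175 and -0.464), and the mitochondrial share was higher in every mutant library than in Col-0. Removing shifts that both mutants share takes away same-direction calls first, so these counts cannot decide on length or organelle transcripts. Without smax1smxl2 replicate 1, whose counts differed from those of its replicates by a chi-square per degree of freedom of 17.1 and 22.3, against 4.38 between replicates 2 and 3 (in Col-0 9.63 and 8.99 against 4.09, and in bbx2021 11.1 and 15.5 against 7.39), the opposite calls were 440, below the 499 of independent lists, so the excess may rest on that library. Without it opposite calls still exceeded independent lists at 2-fold or more (30 against 8.45) and with length and GC offsets (489 against 379), though same-direction calls did so too (54 against 8.88, and 526 against 372), so its part and whether the excess is biological stay open. The excess lay mainly among genes higher in bbx2021 and lower in smax1smxl2 (202 against 115 for independent lists). The reverse group was near its value (74 against 63.7). Genes annotated to flavonoid synthesis were over-represented in that reverse group: 3 of the 74, MYB12, F3H and CHIL, against 0.0855 by chance (exact hypergeometric p = 8.33e-05). FLS1, TT4 and 4CL3, also lower in bbx2021 and higher in smax1smxl2, were not counted under that annotation.

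In 24 genes all 3 libraries of 1 genotype stood at 0 counts, or above 0 in 1 genotype alone, with a mean of at least 20 counts in at least 1 genotype. Of these, 21 had a near-identical copy or an overlapping gene, against 13.6% of 500 random genes, so reads shared with another gene may account for many of them. Linkage to the loci mutated in the genotype that stood apart was argued against as the main source, since 0 of the 24 lay within 2 Mb of such a locus. Loci mutated in the other genotype were not counted. DIR1, at 0 in bbx2021, overlaps AT5G48480.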
